A study of Mus musculus with 2 samples.

How the data were processed

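Single-cell RNA was measured in CD11c+ cells sorted from the mesenteric lymph nodes of C57BL/6J mice with colitis induced by dextran sulfate sodium (DSS). CD11c is a surface integrin carried by dendritic cells and by some other immune cells, and the sort sets which cells can appear in the libraries. There were 2 groups with 1 library each, PBS and lysine, assigned from the treatment given in the labels. The labels do not state how many mice went into a library. Libraries were made with the Chromium Single Cell 3ʹ v3 chemistry, per the labels' protocols.

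The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene row and barcode, with no normalization. They were written by Cell Ranger 7.1.0, per the file headers. The submitters' processing notes instead list Cell Ranger 4.0, Seurat 3.2.0 and the genome build GRCh38, a human build, for these mouse samples, so the version and build behind the counts are uncertain. Whether intronic reads were counted is not given in the sources used here. Each matrix has 33954 rows, and the lowest barcode total in each library is 500 UMIs. The matrices do not pair their rows with gene names, so no gene is named, no cluster is given a cell type, and the gene lists and cell type markers fixed before the data were examined were not used here. Rows are given by their number in the matrix, and clusters by number in order of size.

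Barcodes with at least 500 UMIs and 200 detected rows were kept, which removed 6 barcodes in the PBS library and 10 in the lysine library. Doublets were scored per library with Scrublet in scanpy 1.11.5. The automatic score threshold was 0.209 in the PBS library and 0.508 in the lysine library, where it marked 1 barcode and so did not work. The PBS threshold was therefore used for both libraries, a choice made after the data were seen, and removed 423 barcodes (3.50%) from PBS and 360 (2.67%) from lysine. This left 11665 cells in the PBS library and 13121 in the lysine library.

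Cells of both libraries were clustered together without batch integration. Counts were scaled to 10000 UMIs per cell and log transformed, 2000 variable rows were reduced to 30 principal components, and a graph of 15 neighbours was partitioned with leidenalg 0.10.2 at resolution 1. Shares of cells carry exact Clopper-Pearson 95% intervals. Summed UMIs per library were scaled to CPM, the UMIs of a row per 1000000 UMIs of its library, with exact Poisson 95% intervals, and the log2 ratio of lysine over PBS was taken with 1 CPM added to both. A row was ranked if it reached 10 CPM in 1 library and 100 UMIs over both. The size threshold was 2-fold. The same sums were made within each cluster with at least 100 cells in each library. For detected rows per cell, each cell was thinned to 2000 UMIs without replacement and shallower cells were left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

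With 1 library per group there is no replicate and no test. All intervals cover counting error only, and a difference between the libraries cannot be assigned to the treatment. A count of rows past 2-fold describes these 2 libraries. Of rows beyond the size threshold, the text names by number the 2 highest and the 2 lowest by log2 ratio of the library totals, a rule fixed before the data were examined. The 1.5 times size used to describe cluster shares, the definition of a row that leads a cluster (at least 4-fold over all other cells and detected in at least 25% of the cluster's cells), the limit of 50% of UMIs in 1 barcode, and the count of clusters in which a row was higher or lower (at least 90% of those with at least 10 UMIs of the row) were set after the data were seen.

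The row ratios were tested on simulated Poisson counts drawn from the pooled means and library sizes, with 200 changed rows, 100 of them by 4-fold and 100 by 1.5-fold. The simulation holds counting error only, with no variation between libraries and no UMIs gathered in 1 barcode. It therefore gives no rate of false differences for the real libraries. In the simulated library totals, over 8669 rows, 99% of the 4-fold rows and 0% of the 1.5-fold rows passed the 2-fold size, as did 0 of 8470 unchanged rows. In the simulated cluster 20, the smallest cluster summed, over 1219 rows, 69% of the 4-fold rows and 2% of the 1.5-fold rows passed, as did 0 of 1064 unchanged rows.

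Alternatives planned in advance were no filter and a stricter filter of 1000 UMIs and 500 rows, thinning to 1000 or 3000 UMIs, resolutions of 0.5 and 1.5, 4000 variable rows, doublets kept, clustering of thinned cells, median-of-ratios scaling, every cell weighted equally, 10 or 0.1 CPM added, no expression minimum, all barcodes, and cluster shares held equal. Added after the data were seen were each library's own doublet threshold, clustering without rows that differed between the libraries, clustering of cells with at least 2000 UMIs, and totals without 10 barcodes or without the most abundant row.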

Results

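CD11c+ cells were sorted on day 7 from the mesenteric lymph nodes of mice with DSS colitis, an injury of the gut epithelium that draws immune cells to the draining nodes. Daily PBS or daily lysine at 100 mg/kg began once DSS had been given for 2 days. The comparison asks how lysine supplementation relates to the CD11c+ cells sorted from these nodes. Each group had 1 library. The PBS library held 12094 barcodes and 73227486 UMIs over 23511 rows with a UMI, and the lysine library held 13491 barcodes and 79427235 UMIs over 23532 rows. After filtering, 11665 PBS and 13121 lysine cells remained, with 68351486 and 74883616 UMIs. The median depth was 4894 UMIs per cell (95% interval 4823 to 4964) in PBS and 4695 (4611 to 4772) in lysine. The files do not pair rows with genes, so clusters and rows are described by number. There are no replicates, so every interval below covers counting error only.

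Cells of the lysine library carried fewer detected rows than cells of the PBS library at the same depth. With each cell thinned to 2000 UMIs, the median was 1169 rows per cell (1167 to 1172) in PBS and 1112 (1109 to 1115) in lysine, a ratio of 0.951. The difference ran through the sorted population: the median was lower in lysine in 18 of the 18 clusters with at least 100 thinned cells per library, with ratios from 0.945 to 0.981. Thinning left out 1660 PBS cells (14.2%) and 2213 lysine cells (16.9%). Without thinning the medians were 2150 (2129 to 2171) and 1994 (1964 to 2019), a ratio of 0.927. The most abundant row took 2.38% of UMIs in PBS and 3.67% in lysine.

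The composition of the sorted CD11c+ cells differed between the libraries. The 24786 cells formed 26 clusters, of which 20 had at least 100 cells in each library. Clusters 9, 3, 6 and 11 were at least 1.5 times larger in the lysine library and together made up 12.2% of PBS cells (11.6% to 12.8%) and 27.5% of lysine cells (26.7% to 28.2%). Clusters 17, 15, 16 and 18 were at least 1.5 times smaller there, together 14.6% of PBS cells (13.9% to 15.2%) and 8.09% of lysine cells (7.63% to 8.57%). Cluster 10, with a ratio of 1.21, was past the 1.5 times size in 6 of the 8 alternatives that allowed a match, where it ranged from 1.11 to 1.96, and cluster 18 was past it in 7 of 9. The share of cells that would have to change cluster to make the libraries alike was 19.99 percentage points.

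Cluster 9 differed by the highest ratio among the 20 clusters, with 1.69% of PBS cells (1.46% to 1.94%) and 6.58% of lysine cells (6.17% to 7.02%), a ratio of 3.90. This ratio moved between 2.47 and 7.50 with the processing, always above 1. Cluster 3 made up 3.94% (3.60% to 4.31%) of PBS cells and 9.86% (9.36% to 10.4%) of lysine cells, a ratio of 2.50 that ranged from 2.07 to 3.93 in the alternatives. Cluster 6 made up 3.81% (3.47% to 4.17%) and 6.57% (6.15% to 7.01%), and cluster 11 2.75% (2.46% to 3.07%) and 4.45% (4.10% to 4.82%). Cells of cluster 3 were shallow, with median depths of 1036 UMIs in PBS and 1646 in lysine, and cluster 9 had 1690 and 2959. Cluster 6 was deep, with 8471 and 10273 UMIs and 227 leading rows. Clusters 9, 3 and 11 had 40, 33 and 7 leading rows, so cluster 11 was set apart by few rows.

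Among the 20 clusters, cluster 17 had the lowest ratio, from 3.67% of PBS cells (3.34% to 4.03%) to 1.91% of lysine cells (1.68% to 2.15%), a ratio of 0.519, with 261 leading rows and depths of 6681 and 7022 UMIs. Clusters 15, 16 and 18 had ratios of 0.541, 0.554 and 0.616. Cluster 1, the most populous, fell short of the 1.5 times size, with 19.1% of PBS cells (18.4% to 19.8%) and 13.3% of lysine cells (12.7% to 13.9%), a ratio of 0.695. Over the 20 clusters, the intervals of both libraries did not overlap in 7 clusters larger in lysine and 10 clusters smaller in lysine. The shares of a library are parts of a whole, so a rise in some clusters lowers others, and these counts are not independent. When clustering was repeated without the rows that differed between the libraries, an alternative added after the data were seen, 4 clusters were again at least 1.5 times larger and 4 at least 1.5 times smaller, and the ratios of clusters 9 and 17 were 3.28 and 0.528.

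**Figure D1:**
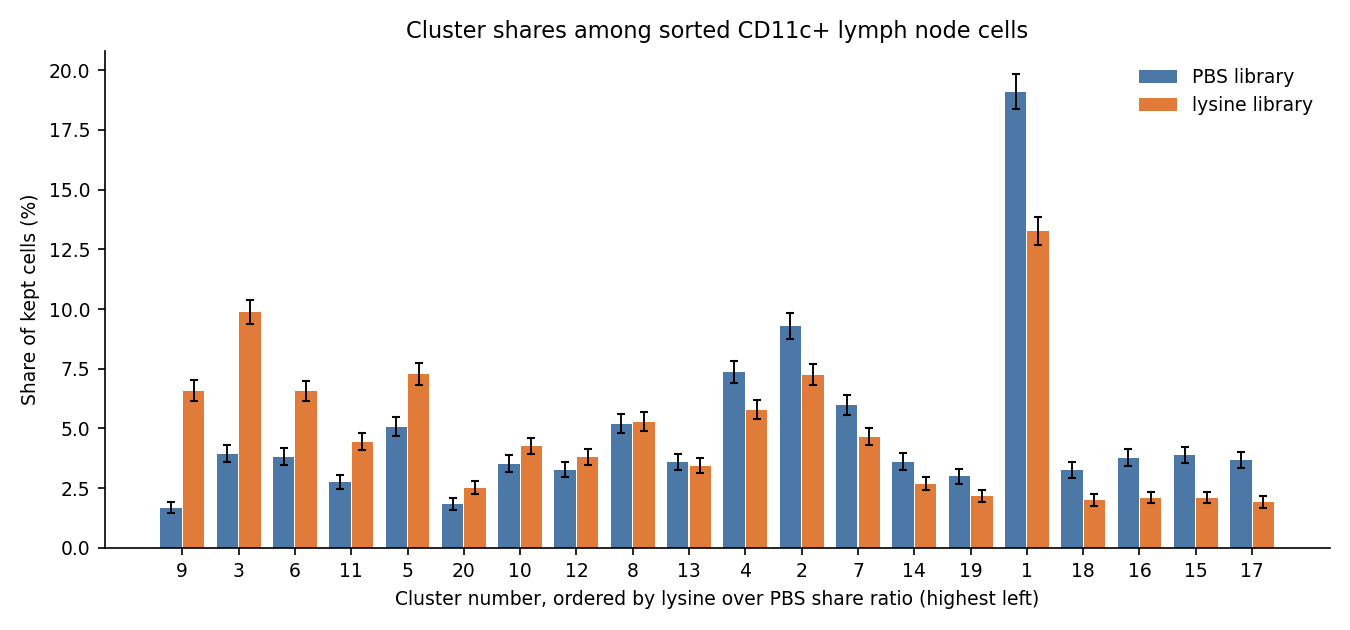
Share of kept cells, in percent, in each of the 20 clusters with at least 100 cells in each library, for the PBS and lysine libraries, ordered by the ratio of the shares. Bars start at 0 and error bars are exact Clopper-Pearson 95% intervals for counting error only; cluster 9 stands at 1.69% in PBS and 6.58% in lysine, and cluster 17 at 3.67% and 1.91%.

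Among the 6 smaller clusters, cluster 26 held 23 PBS cells and 0 of 13121 lysine cells, which allows a share of up to 0.0229% in lysine by the limit of 3 counts, and up to 0.0281% by the Clopper-Pearson interval. All of its cells came from 1 library, so it is not compared between the groups, and its median doublet score of 0.120 was the highest of the 26 clusters.

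Summed over all cells, expression in both libraries was close for most rows, and a short list stood apart. Of 8839 ranked rows, 28 were at least 2-fold higher in lysine and 16 at least 2-fold lower, together 0.498%. The median log2 ratio was -0.14, with quartiles of -0.29 and 0.05, and the correlation of log2 CPM across rows, which are not independent replicates, was 0.997. Median-of-ratios scaling brought the median to -0.0048 and gave 46 higher and 10 lower rows. Of the 28 higher rows, 17 lead cluster 6, 15 lead cluster 9, 1 leads cluster 3 and 0 lead cluster 11, the 4 of the 20 clusters at least 1.5 times larger in lysine. Another 2 lead cluster 10 and 1 leads the small cluster 25, and a row can lead more than 1 cluster. Of the 16 lower rows, 4 lead cluster 17, 3 lead cluster 15 and 0 lead clusters 16 and 18, the clusters at least 1.5 times smaller in lysine. Lower rows also lead cluster 12 (3 rows) and the small clusters 22 (3), 23 (2), 24 (2) and 26 (1). Holding cluster shares equal leaves out cluster 26, which has no lysine cells. With cluster shares held equal, 5 of the 28 higher rows and 9 of the 16 lower rows still differed by at least 2-fold, but outside 4 higher rows held mostly by 1 barcode this was 1 of 24.

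**Figure D2:**
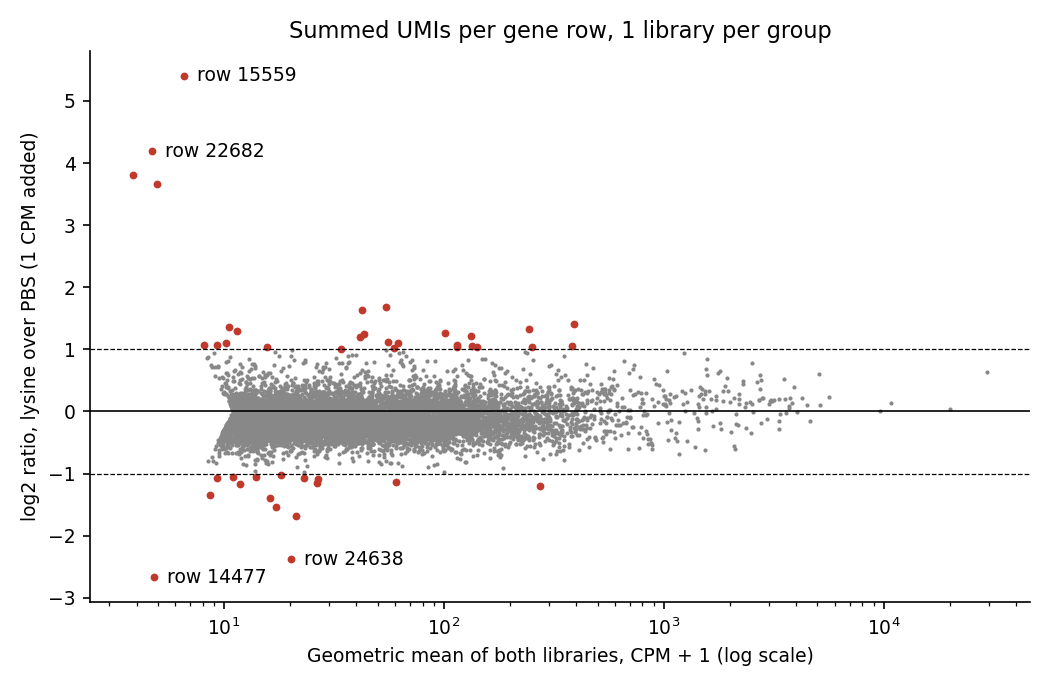
Log2 ratio of lysine over PBS, with 1 CPM added, against the geometric mean of CPM + 1 in both libraries on a log axis, for each of 8839 ranked gene rows. Red points are the 28 rows at or above 1 and the 16 at or below -1 (dashed lines); rows 15559 and 22682 lie at 5.40 and 4.19, and rows 14477 and 24638 at -2.67 and -2.38.

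The highest ratios belonged to rows held almost entirely by a few lysine barcodes. Row 15559 had 1 UMI in PBS and 3141 UMIs in 44 lysine cells, or 0.0146 CPM (0.00037 to 0.0815) and 41.9 CPM (40.5 to 43.4). Its log2 ratio was 5.40, and the ratio of CPM without the added value was 2867, with a counting interval of 514 to 113276. A single barcode in cluster 20 carried 2294 of these UMIs, 73.0%. Row 22682 had 7 UMIs in PBS and 1429 in 20 lysine cells, a log2 ratio of 4.19, and 70.7% of its lysine UMIs were in 1 barcode of cluster 20. In all, 4 of the 28 higher rows had over 50% of their UMIs in 1 barcode. The 10 barcodes with the most UMIs of row 15559 held 98.9% of them, and 9 of the 10, all in the lysine library, carried UMIs of all 4 of the highest rows. The last of the 10 is the PBS barcode with the row's single PBS UMI, tied with other cells of 1 UMI. Without these 10 barcodes, chosen after the data were seen, the log2 ratios of rows 15559 and 22682 were 0.55 and 0.06, while 24 of the 28 higher rows were still at least 2-fold higher.

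The other 24 higher rows had a median log2 ratio of 1.10, and 17 of them were higher in lysine in at least 90% of the clusters where they had at least 10 UMIs. In the 16 clusters that none of these rows lead, their summed UMIs per cell ranged from 1.91 to 11.6 in PBS and from 2.50 to 16.5 in lysine, and the lysine over PBS ratio lay between 1.23 and 1.97. These ratios are per cell and are not adjusted for depth. Cluster 8, with the highest ratio, had median depths of 2782 UMIs in PBS and 2956 in lysine. Cluster 11, with the lowest, had 3445 and 3299.5.

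The 2 rows with the lowest ratios were lower in most clusters. Row 14477 had 762 UMIs in PBS and 68 in lysine, or 11.1 CPM (10.4 to 12.0) and 0.908 CPM (0.705 to 1.15), a log2 ratio of -2.67. Its level in cluster 3, the highest among the 20 clusters, was 148 CPM (123 to 177) in PBS and 11.0 CPM (7.45 to 15.6) in lysine. Row 24638 had 3082 and 589 UMIs, or 45.1 CPM (43.5 to 46.7) and 7.87 CPM (7.24 to 8.53), a log2 ratio of -2.38. It was highest in cluster 12, with 286 CPM (270 to 304) in PBS and 50.9 CPM (44.9 to 57.5) in lysine, and in cluster 5, with 226 CPM (206 to 247) and 29.2 CPM (23.3 to 36.1). Both rows were lower in lysine in 17 of the 17 clusters where they had at least 10 UMIs. In PBS, row 14477 lay near 1 level in several clusters, with 8.58, 8.48 and 8.22 CPM in clusters 1, 2 and 6. Outside cluster 3 it ranged from 3.94 CPM in cluster 15 to 27.5 CPM in cluster 16. Low counts in many clusters can come from free RNA in the droplets, which was not tested for either row alone. The 16 lower rows reached 10 UMIs in as few as 2 and as many as 20 clusters, and the highest share of a row's PBS UMIs in 1 barcode was 27.7%. With 10 CPM added, row 14477 stood at -0.96 and row 24638 at -1.62.

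**Figure D3:**
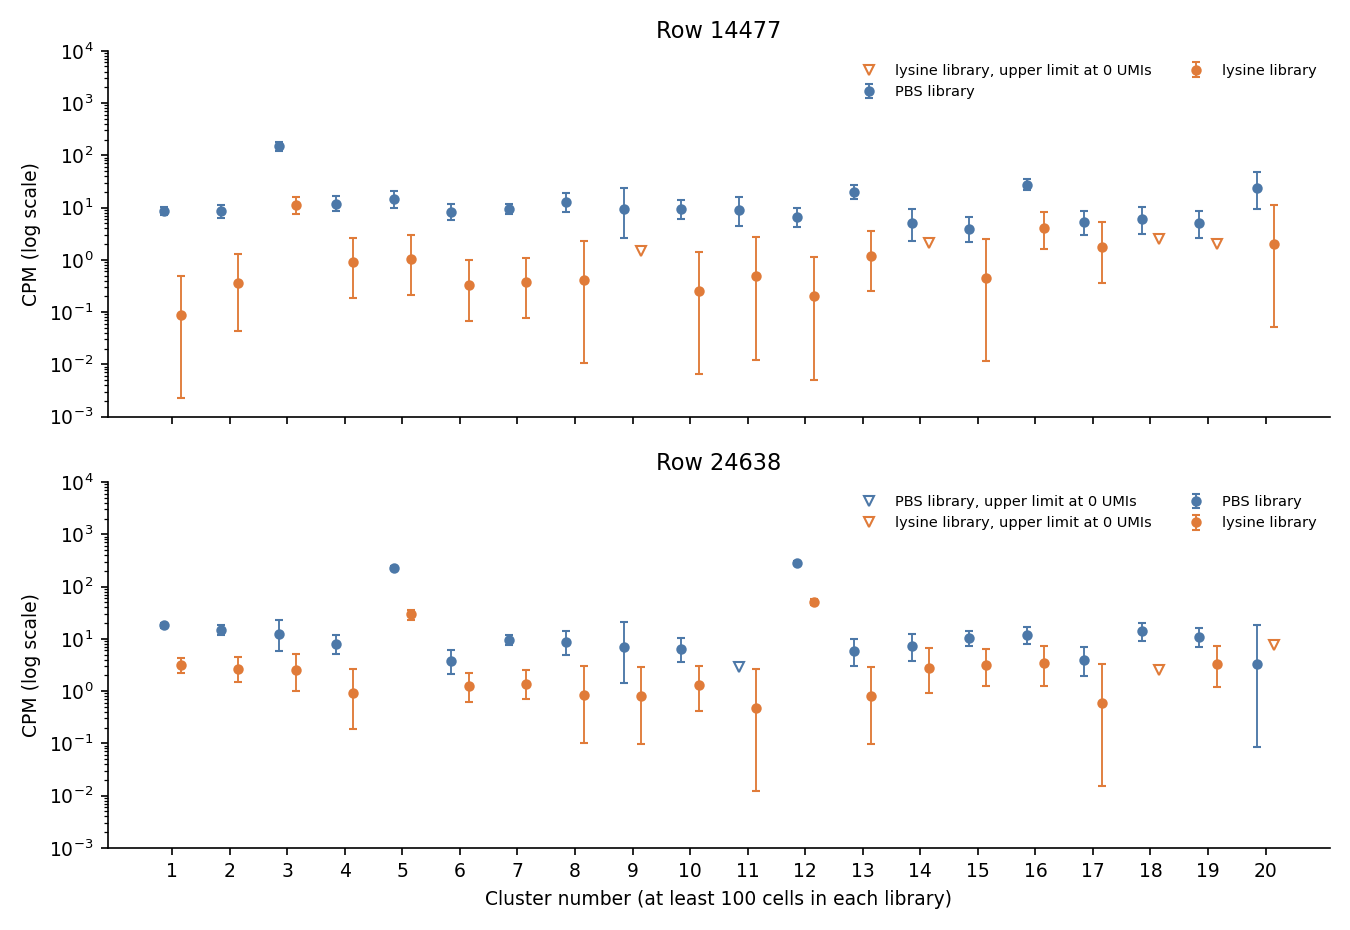
CPM of rows 14477 and 24638, on a log axis, in each of the 20 clusters with at least 100 cells in each library, in the PBS and lysine libraries. Bars are exact Poisson 95% intervals for counting error only and open triangles mark the upper limit where no UMI was counted; row 14477 in cluster 3 stands at 148 CPM in PBS and 11.0 CPM in lysine, and row 24638 in cluster 12 at 286 and 50.9 CPM.

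Within clusters, rows lower in the lysine library outnumbered rows higher in it in 15 of the 20 clusters, and the reverse held in 5. Over the 20 clusters, 345 differences of at least 2-fold were toward lysine and 641 toward PBS, from 247 and 484 distinct rows. Clusters 5 and 10 each gave 108 of the 641. The share of ranked rows past 2-fold ran from 0.180% in cluster 1, with 13175943 PBS and 11162776 lysine UMIs, to 5.18% in cluster 20, with 299220 and 491205 UMIs. After thinning to 2000 UMIs per cell the counts were 173 and 202, and with 10 CPM added they were 140 and 248. The median log2 ratio was below 0 in 19 of the 20 clusters, and the counts within clusters were not repeated under median-of-ratios scaling. The excess of lower rows was therefore not separated from this offset or from unequal UMIs. Cluster 9 had 17 higher and 55 lower rows, with 424813 PBS and 2492717 lysine UMIs. Cluster 8, also with fewer PBS UMIs (1882568 and 2399977), had 33 higher and 9 lower rows.

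Among rows that reached 10 CPM and 100 UMIs within a cluster, at least 2-fold differences in 5 or more clusters were found for 8 rows lower in lysine and 6 rows higher in it. This leaves out clusters where a row had few UMIs: row 14477 counted in 1 cluster and row 24638 in 4. A single row, picked out after its values were seen, was at least 2-fold lower in all 20 clusters. It had 415 CPM (410 to 420) in PBS and 180 CPM (177 to 183) in lysine, a log2 ratio of -1.20 over all cells and of -1.41 to -1.06 within the clusters. With cluster shares held equal its log2 ratio was -1.26.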

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

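Each library's own doublet threshold, clustering without rows that differ, the restriction to cells with at least 2000 UMIs, and totals without 10 barcodes or the most abundant row were chosen after the data were seen. All 8 clusters past the 1.5 times size stayed on their side of 1 in the alternatives that allowed a match, and of 174 share ratios 156 stayed within their interval, and 18 moved. Outside these 8 clusters, 7 ratios crossed 1, in clusters 8, 13 and 20. The ratio of cluster 9 was 2.47 at resolution 0.5, 7.50 in thinned cells and 7.40 when cells with at least 2000 UMIs were clustered anew, and the distance between the libraries was 21.5 points with the stricter filter. The ratio of cluster 20, 1.38, ranged from 0.795 to 1.25 in the alternatives and has no stable direction. Median depths were 4993 (PBS) and 4794 (lysine) UMIs without a filter and 5149 and 5068 with the stricter one (the first setting keeps doublets and the second removes shallow cells). At 3000 UMIs the ratio of detected rows was 0.956. Median-of-ratios scaling gave 46 higher and 10 lower rows and a median of -0.0048, 10 CPM added gave 13 and 4, cluster shares held equal gave 5 higher rows, and no expression minimum gave a median of -0.029. Within clusters, thinning gave 173 higher and 202 lower and 10 CPM added gave 140 and 248. Of 44 values for the 4 named rows, 0 changed sign and 16 moved. An unchanged sign does not mean a stable size: without the 10 barcodes, rows 15559 and 22682 fell to 0.55 and 0.06. Except where the alternative removes low counts, rescales all rows or removes share differences by its construction, the cause was not tested. Low counts limit the row ratios within small clusters. The gene list alternatives were not run, as rows carry no names. No paired analysis was possible because each group has 1 library.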

Other observations

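Tests chosen only after the result was seen were the restriction of cluster 9 to deep cells, the share test of the 24 higher rows, the scaling test of the 16 lower rows, the tests of the difference across clusters for free RNA, and the statements on treatment and handling. The others were set down before their values were seen.

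Cluster 9 made up 1.69% of PBS cells and 6.58% of lysine cells. Lysine barcodes near the 500 UMI limit do not make up the excess. The share ratio was 6.69 among cells with at least 2000 UMIs in the clusters as first made. Cells of cluster 9 were shallower in PBS (median 1690 UMIs) than in lysine (2959), so this cut removed a larger part of them in PBS. It cannot tell whether PBS cells of the cluster were lost below 500 UMIs, which stays open. Clustering on rows that differ between the libraries does not account for the excess, since the matched ratio without those rows was 3.28. Droplets that hold free RNA stay open: the 10 rows that led the cluster in PBS had a median fold of 5.08 over other cells in the lysine library, but joint clustering fixes this outcome, and 20 of the 20 clusters passed the bound of 2-fold. A shift in composition with lysine treatment may underlie the pattern, but with 1 library per group it cannot be told apart from differences between mice, sorts or library preparations.

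The 24 rows higher in lysine outside those held by 1 barcode had a median log2 ratio of 1.10. Cluster shares were not the whole difference: with shares held equal the median was 0.54 (quartiles 0.37 and 0.69), so these rows as a set no longer reached 2-fold but stayed above 0. Free RNA from the clusters these rows lead stays open: across the 16 clusters they do not lead, the difference between the libraries ranged over 8.31-fold in UMIs per cell but 2.87-fold in CPM, within the 3-fold that free RNA scaling with depth would allow. The level of these rows per cell, the test set down first, ranged over 6.07-fold in PBS and 6.60-fold in lysine, past its 3-fold bound, but that bound takes no account of depth or of a cluster's own expression. A response of many cell populations to lysine was not tested separately and stays open.

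The 16 rows lower in lysine had a median log2 ratio of -1.16. Median-of-ratios scaling shifts all rows by nearly the same amount, and moved the median of all ranked rows from -0.14 to -0.0048. That shift is small beside the ratios of these 16 rows. Their median became -1.04 with the highest at -0.90, and 10 of the 16 were still at least 2-fold lower. Because the rows were chosen at -1 or below, this outcome followed from the size of the shift and could not have come out otherwise. Cluster shares were not the whole difference for the set, since with shares held equal the median was -1.05 (quartiles -1.29 and -0.63) and 9 of the 16 were still at least 2-fold lower, but they stay open for the 4 rows above -0.5, which reached up to 0.10. Free RNA richer in the PBS library was tested only on the sum of these rows. Across the 17 clusters that none of the 16 rows lead, the difference ranged over 7.75-fold in UMIs per cell and 4.07-fold in CPM. Beyond counting error the range in CPM was 3.46-fold, past a 3-fold bound set after the result was seen. By this bound free RNA was not the whole difference for the sum. A single row, with 415 CPM in PBS, holds most of the summed UMIs, so free RNA stays open for the other rows. The level of the 13 rows lower in at least 90% of clusters, the test set down first, covered all 20 clusters. It ranged over 8.97-fold in PBS and 7.49-fold in lysine, past its 3-fold bound. That bound takes no account of depth or of a cluster's own expression, so the level cannot decide the question. The treatment, the mice and the handling of 1 library cannot be told apart with 1 library per group.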
